A study of Mus musculus with 15 samples.

How the data were processed

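Total RNA from mouse colon was sequenced in 15 libraries of 5 groups with 3 libraries each, and the series was analysed from 1 deposited table of counts. The values are whole-number counts per gene, not normalised, as deposited by the authors. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a SMARTER kit. Per the submitters' processing notes, the genome builds named were GRCm38 and mm10. The aligner, the counting tool and its use of strand are not given in the sources used here. Reads of near-identical genes (the Ang, Clca4, Mcpt and Hspa1 genes, pancreatic trypsins, and mitochondrial genes with nuclear copies) may therefore be split between copies, and values of such genes are uncertain.

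Samples were grouped by their labels, and table columns were matched to samples by name. The table holds 56859 genes, of which 23552 had no count in any library. Genes with low counts were removed with edgeR's filterByExpr, which left 18038. All 15 libraries were fitted together in R 4.3.3 with edgeR 4.0.16 (TMM normalisation, quasi-likelihood fit and test, glmQLFit and glmQLFTest), for 10 pairwise comparisons and an F test over the 5 groups. Calls are genes with a Benjamini-Hochberg adjusted p below 0.05. CPM values are counts scaled to library size by edgeR's cpm with TMM factors, given as mean ± SD of 3 libraries. Fold changes are on the log2 scale, with an SE taken as the fold change over the square root of its F statistic.

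The 37 gene lists were fixed before the data were examined. Each was tested with fry in limma 3.58.1, adjusted within a comparison, and again with camera using an estimated correlation. Of 370 pairs of list and comparison 143 were called by fry and 10 of these by camera, so most list calls rest on fry's test of whether members move one way on balance, which does not compare the list with other genes. The text describes 46 of the pairs called by fry, chosen after their values were seen. Named genes followed a rule set beforehand: per comparison the 6 largest rises and 6 largest falls (3 and 3 between saline days) among called genes with a mean of at least 2 CPM, no overlap between the groups and a symbol that is neither a predicted or clone name nor an immunoglobulin or T cell receptor segment. Results of some of these genes are not reported here. The rule also took up to 4 members with the smallest p of each list described, Apex1, and the 5 most abundant genes. Coordinates are from GENCODE M21 (GRCm38), matched by symbol: 49209 of 55311 symbols were found, and 1 of the 1548 genes given only by an Ensembl ID.

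Where a group had no count of a gene, the fold is a lower bound from a floor of 3 counts over the group. With 1 to 3 counts the ratio has a 95% counting interval. Floors and intervals cover counting error only. With 3 libraries against 3 an exact permutation test cannot go below 0.1, and chance leaves 10% of genes without overlap between the groups. Non-overlapping genes made up between 17.0% (APX3330 against saline D100) and 42.5% (saline D48 against Control) of those tested. Within groups, pairs of libraries differed by more than counting noise, so none was taken as 1 library deposited more than once.

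Alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 test (version 1.42.0), the replicate number as a block, only the 2 groups of a comparison in the fit, limma-voom with sample quality weights, a smooth muscle score as a covariate, a change of at least 1 on the log2 scale, and each library left out in turn. An adipocyte score as a covariate and fits without the libraries holding squamous or pancreatic transcripts were added after seeing the data, as were the median folds and SEs of called genes before and after each covariate. The fit was tested on simulated counts with known changes. Overlaps were set beside those of independent lists, and fold relations between comparisons with shared libraries beside 20 simulations of unchanged groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.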

Results

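RNA was sequenced from the colon of male C57BL/6J mice in a model of colitis-associated colorectal cancer. In this model azoxymethane (AOM), a colon carcinogen, is injected once, and dextran sulfate sodium (DSS), which injures the colonic epithelium, is then given in the drinking water in cycles. The labels give 10 mg/kg AOM on day 0 and 2.5% DSS on days 7 to 11, 28 to 32 and 49 to 53. APX3330 (also called E3330), an inhibitor of the redox function of the DNA repair enzyme APE1/Ref-1 encoded by Apex1, was injected at 25 mg/kg on the DSS days, and saline served as the placebo. The 15 libraries fell into 5 groups of 3: Control, saline D27, saline D48, saline D100 and APX3330. The series describes its design as a comparison of APX3330 with saline in this model.

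Several labels leave the design open. The Control libraries are labelled as wild type only, while the shared protocol says that every mouse received AOM, so their treatment is not settled here. The days come from the sample descriptions, and the titles name the D48 group as cycle 1 and the D100 group as cycle 2, although day 48 follows the second DSS period of the protocol. No day is given for the APX3330 group. The titles of the APX3330 and D27 groups name no cycle. They differ only in E3330 or saline, which pairs these groups by title but states no day. APX3330 was therefore compared with each saline group on equal terms, and any difference between them can hold a difference in day. The labels do not say outright that the libraries came from separate animals, so p-values measure the spread between these libraries.

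Total counts per library ranged from 13548661 to 17919613. Of the 56859 genes in the table, 18038 had enough counts to test. The 5 most abundant genes were Clca1, Fcgbp and Muc2, which are products of mucus-secreting goblet cells, the mitochondrial gene mt-Co1, and Lypd8, a colonocyte surface protein. Muc2 took 0.253% ± 0.0150 of the counts in Control (SD, n = 3, as for every mean below) and 1.35% ± 0.136, 1.07% ± 0.169, 1.84% ± 0.519 and 1.15% ± 0.110 in saline D27, D48, D100 and APX3330. Clca1 took 0.235% ± 0.0383 in Control and 2.70% ± 0.996 in APX3330, with 2.10% ± 0.130, 0.974% ± 0.398 and 2.60% ± 0.324 in the saline groups in order of day. Fcgbp rose from 0.375% ± 0.00989 in Control to 1.82% ± 0.312 at D27, 1.41% ± 0.475 at D48, 2.21% ± 0.302 at D100 and 2.10% ± 0.446 with APX3330. The share of mt-Co1 was 1.86% ± 0.0437 in Control and 1.04% ± 0.118 at D48, with 1.52% ± 0.397 at D27, 1.55% ± 0.0254 at D100 and 1.91% ± 0.234 with APX3330. Lypd8 took between 0.613% ± 0.0212 (D100) and 0.918% ± 0.0543 (Control), with 0.863% ± 0.0704, 0.884% ± 0.0524 and 0.620% ± 0.0571 at D27, at D48 and with APX3330.

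Transcripts of other tissues were present in some libraries. Genes of the exocrine pancreas made up 4.02% and 1.10% of the counts in saline D48 replicates 2 and 3 and at most 0.0357% in the other 13 libraries. Genes of squamous epithelium made up 0.130% and 0.0623% in Control replicates 1 and 3 and 0.0997% in saline D100 replicate 1, against at most 0.0121% elsewhere. The posterior homeobox gene Hoxd13, whose level follows position along the gut, stood at 242 ± 13.9 CPM in Control and at 90.4 ± 3.53, 89.6 ± 16, 63.7 ± 29.5 and 95.6 ± 36.2 CPM in saline D27, D48, D100 and APX3330. Hoxd13 was chosen after its values were seen. Each count of genes below was repeated without the libraries holding these transcripts, and with 1 library left in a group the filter on low counts kept more genes, which made some lists longer. The single genes said to lead a comparison had the largest fold changes among called genes with a mean of at least 2 CPM, no overlap between the groups and a symbol that is neither a predicted or clone name nor an immunoglobulin or T cell receptor segment. Some genes outside that rule moved more.

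Apex1 (chromosome 14, 50924968 to 50927139, plus strand, GRCm38), which encodes the target of APX3330, was expressed at low levels in every group. Differences between groups were not called, which does not show that the levels were equal. Its mean was 4.76 ± 0.971 CPM in Control, 5.86 ± 1.37 in saline D27, 5.96 ± 1.94 in saline D48, 5.60 ± 1.02 in saline D100 and 4.27 ± 0.926 in APX3330. Apex1 was not called in any of the 10 comparisons, with log2 fold changes from -0.48 ± 0.286 (SE, APX3330 against saline D48, edgeR adjusted p = 0.260) to 0.32 ± 0.284 (saline D48 against Control, adjusted p = 0.431). The base excision repair list was not called by fry's test of one direction in any comparison, with adjusted p of at least 0.167. Without regard to direction its fry adjusted p was below 0.05 in 8 of the 10 comparisons. It was 3.03e-07 for saline D48 against Control, where 4 of 17 members were higher and 1 lower, and 8.73e-06 for APX3330 against saline D48, where 3 were higher and 1 lower. Over all 18038 genes 4916 and 3557 were called in these comparisons, so the share called on the list was near that of all genes. The fry test does not compare the list with other genes.

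**Figure D1:**
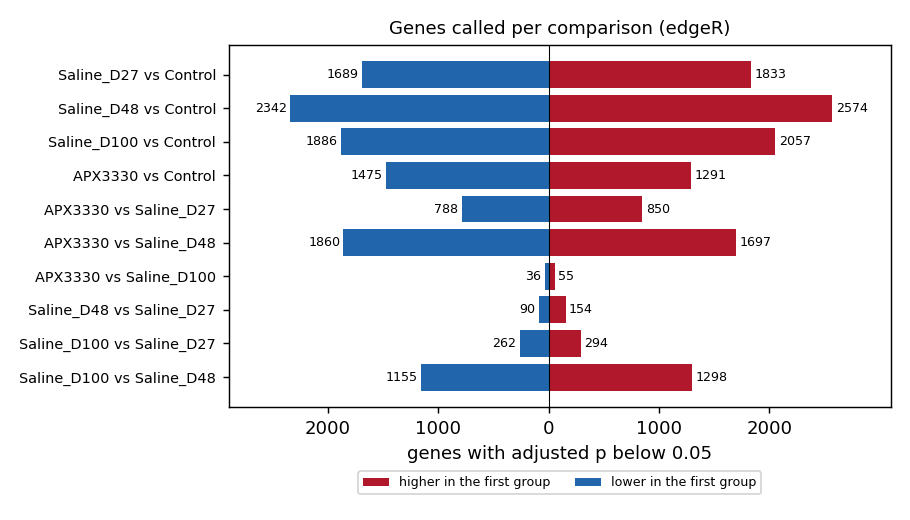
Number of genes with an edgeR adjusted p below 0.05 in each of the 10 comparisons (x axis, genes; red bars higher and blue bars lower in the first group named). Saline D48 against Control has 2574 higher and 2342 lower genes, and APX3330 against saline D100 has 55 and 36.

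The comparison of saline D27 with Control, whose AOM treatment is open, asks how the colon differed at the earliest saline day. Secretory and antimicrobial genes led the rises. Retnlb, a goblet cell protein that acts on bacteria (chromosome 16, 48816856 to 48818892), went from 0.2497 ± 0.0467 CPM in Control to 1078 ± 360 CPM, a log2 fold change of 12.04 ± 1.38 (SE, edgeR adjusted p = 1.00e-04). The antimicrobial ribonuclease Ang4 rose from 0.767 ± 0.219 to 1998 ± 319 CPM. Itln1, a lectin of the intestinal mucus, rose from 0.544 ± 0.0362 to 45.5 ± 9.54 CPM. Pla2g4c, a phospholipase, rose from 0.525 ± 0.115 to 300 ± 164 CPM. Pnliprp2, a lipase-related gene, rose from 1.93 ± 0.451 to 75.2 ± 14.1 CPM. In each, all 3 libraries of one group lay above all 3 of the other. The goblet cell list moved with these genes: 13 of its 15 members rose (14 adjusted over the list alone), among them Muc2 (log2 2.46), Spink4 (3.51) and the transcription factor Spdef (1.84), with a fry adjusted p of 5.95e-05 and an adjusted p = 0.0171 with an estimated correlation.

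Immune genes were also higher at D27. All 7 MHC class II genes rose (7 adjusted over the list alone, fry adjusted p = 0.000843, adjusted p = 0.0787 with an estimated correlation), with Cd74 going from 224 ± 36.5 to 950 ± 171 CPM. Of 17 T cell genes 14 rose (15 adjusted over the list alone, fry adjusted p = 0.00390, adjusted p = 0.168 with an estimated correlation), including Cd4 (log2 1.97) and Cd28 (1.74). Among 13 plasma cell genes 11 rose (12 adjusted over the list alone, fry adjusted p = 0.000843, adjusted p = 0.0787 with an estimated correlation), led by Igha (2.14) and Igkc (2.01). The interferon response list had 13 of 17 members up (14 adjusted over the list alone, fry adjusted p = 0.00208, adjusted p = 0.107 with an estimated correlation), with Mx1 going from 8.11 ± 3.27 to 31.4 ± 4.67 CPM.

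Genes of lipid and drug metabolism and of the circadian clock were lower at D27. Of 15 clock genes 9 fell and 1 rose (10 and 2 adjusted over the list alone, fry adjusted p = 0.000843, adjusted p = 0.0787 with an estimated correlation), including Nr1d1 (log2 -2.54) and Per3 (-1.54). Of 15 genes of fatty acid oxidation and PPAR targets 9 fell and Fabp2 rose (11 and 1 adjusted over the list alone, fry adjusted p = 0.000843, adjusted p = 0.104 with an estimated correlation), with Cpt1a, which admits fatty acids to mitochondria, falling from 415 ± 19.2 to 234 ± 20.2 CPM. Among 14 xenobiotic metabolism genes 7 fell (9 adjusted over the list alone, fry adjusted p = 0.00121, adjusted p = 0.104 with an estimated correlation), led by the efflux pump Abcb1a (-1.49). Of 17 fibroblast and extracellular matrix genes 9 fell and 1 rose (11 and 1 adjusted over the list alone, fry adjusted p = 0.00995, adjusted p = 0.296 with an estimated correlation), with Postn at log2 -0.76. Leading the falls were the skeletal muscle myosin gene Myh8, the keratins Krt1, Krt4 and Krt5, Krtdap and Them5, while the squamous epithelium list was not called (5 of 12 members fell, 10 adjusted over the list alone, fry adjusted p = 0.126, adjusted p = 0.444 with an estimated correlation). All 6 were carried by Control replicates 1 and 3, as with Myh8 at 606 and 265 CPM there and 0.438 CPM in replicate 2. Myh8 had 13414 counts in Control and 2 at D27 (ratio 7362, 95% counting interval 2038 to 60795). Krt1 went from 153 ± 144 to 0.104 ± 0.0384 CPM, Krt4 from 81.4 ± 87.3 to 0.106 ± 0.0439 CPM and Krt5 from 44.5 ± 48.6 to 0.0971 ± 0.0868 CPM. Krtdap had 746 counts against 3 (ratio 273, interval 93.0 to 1327), and Them5 was at least 76.8-fold lower, counted against a floor of 3 counts over the group.

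In total 1833 genes rose and 1689 fell at D27 by edgeR's quasi-likelihood test, 1124 and 1005 with the smooth muscle score as a covariate, and 1025 and 849 with the adipocyte score. Under the smooth muscle score median log2 fold changes went from 0.94 to 0.88 and from -0.58 to -0.56. Median SEs went from 0.208 to 0.230 and from 0.140 to 0.150. With the adipocyte score the median folds were 0.83 and -0.54 and the median SEs 0.238 and 0.159. Without the libraries holding squamous transcripts, which leaves 1 Control library, 210 rose and 200 fell, and 9 of 15 goblet, 2 of 17 T cell, 2 of 13 plasma cell, 9 of 17 interferon response and 5 of 7 MHC class II genes rose, while 4 clock, 2 fatty acid oxidation, 1 xenobiotic metabolism and 2 fibroblast genes fell. Leaving out 1 library gave 1022 higher and 777 lower genes without saline D27 replicate 2, 1172 and 1011 without Control replicate 1, 1265 and 1079 without saline D27 replicate 1, and 1229 and 1116 without Control replicate 3.

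**Figure D2:**
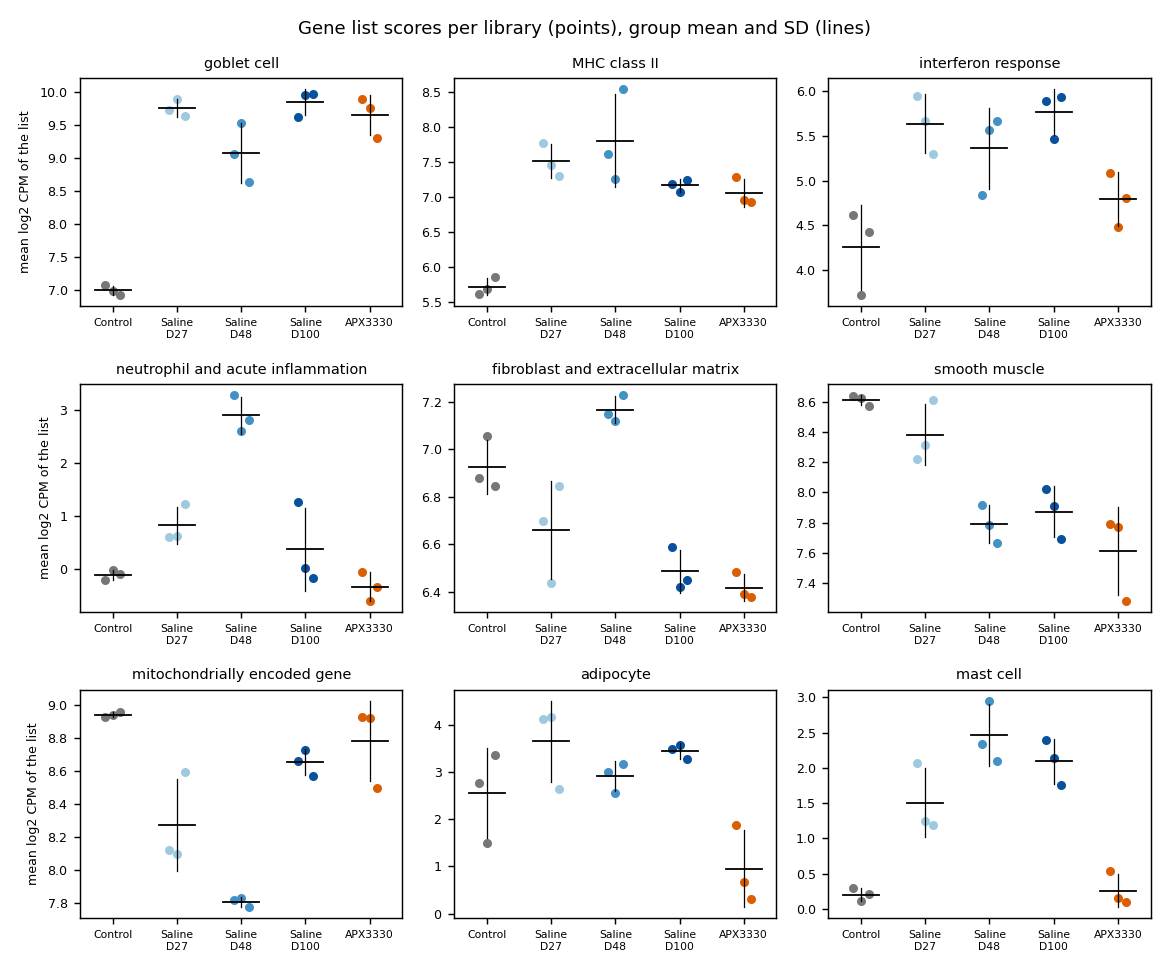
Mean log2 CPM of 9 gene lists in each library (points), by group, with the group mean (horizontal line) and SD (vertical line). The neutrophil list is highest in the 3 saline D48 libraries and the adipocyte list has its lowest group mean in APX3330, although Control replicate 2 lies below APX3330 replicate 1. For goblet cell genes, all 12 saline and APX3330 libraries lie above the 3 Control libraries.

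Saline D48 against Control asks the same of the later day. Acute inflammation genes rose, 13 of 17 on the neutrophil and acute inflammation list (15 adjusted over the list alone, fry adjusted p = 9.15e-05, adjusted p = 0.0539 with an estimated correlation). Saa3, an acute phase protein (chromosome 7, 46711998 to 46715700), rose from 0.312 ± 0.122 to 20.3 ± 6.89 CPM (log2 5.97 ± 0.548, edgeR adjusted p = 1.04e-05), the nitric oxide synthase Nos2 from 4.93 ± 1.77 to 80.4 ± 13.7 CPM and the cytokine Il1b from 1.22 ± 0.411 to 25.0 ± 18.5 CPM. Of 16 macrophage and dendritic cell genes 14 rose (15, with 1 lower, adjusted over the list alone, fry adjusted p = 0.000177, adjusted p = 0.0624 with an estimated correlation), including C1qb (1.67) and Lyz2 (1.84). All 17 T cell genes rose (17 adjusted over the list alone, fry adjusted p = 0.00187, adjusted p = 0.135 with an estimated correlation), Cd4 by log2 2.48 and the inhibitory receptor Ctla4 by 2.56.

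Goblet cell genes rose here too, 14 of 15 (14 adjusted over the list alone, fry adjusted p = 9.15e-05, adjusted p = 0.0539 with an estimated correlation), with Ang4 at 366 ± 449 CPM and Muc2 up by log2 2.13. All 10 mitochondrially encoded genes fell (10 adjusted over the list alone, fry adjusted p = 0.000133, adjusted p = 0.0642 with an estimated correlation), with mt-Nd5 going from 2680 ± 122 to 1181 ± 31.1 CPM and mt-Nd1 from 2892 ± 112 to 1296 ± 94.3 CPM. Smooth muscle genes fell in 11 of 13 cases (12 adjusted over the list alone, fry adjusted p = 0.000504, adjusted p = 0.114 with an estimated correlation), such as Cnn1 (-0.82) and Des (-0.82). Of 15 fatty acid oxidation genes 12 fell (12 adjusted over the list alone, fry adjusted p = 9.15e-05, adjusted p = 0.0624 with an estimated correlation), with Pdk4 at -2.45. The pancreatic enzymes Pnlip, Cela2a, Cpa1, Try5, Cela3b and Ctrb1 led the rises, and their counts came from replicates 2 and 3. Pnlip had no count in Control and was at least 37653-fold higher, Cela2a at least 30176-fold, Cpa1 at least 22213-fold, Try5 at least 14658-fold and Cela3b at least 14289-fold (floor of 3 counts over the group). Ctrb1 had 2 counts in Control against 173126 (ratio 80927, interval 22403 to 668244). The leading falls were again from genes carried by Control replicates 1 and 3, and Myh8 was at least 4783-fold lower. Myh1 had 10108 counts in Control and 3 at D48 (ratio 3604, interval 1233 to 17479), and Klk13 had 270 against 3 (ratio 96.3, interval 32.6 to 470). Mybpc1 fell from 33.1 ± 32.3 to 0.216 ± 0.0863 CPM, Krt1 reached 0.0858 ± 0.0413 CPM, and Krtdap had 746 counts against 3 (ratio 266, interval 90.7 to 1293).

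At D48, 2574 genes rose and 2342 fell. With the smooth muscle score as a covariate 39 rose and 18 fell, while the median log2 fold changes of the 2574 and 2342 genes went from 0.97 to 0.78 and from -0.64 to -0.47 and their median SEs from 0.210 to 0.418 and from 0.146 to 0.272. Without replicates 2 and 3, which leaves 1 library, 984 rose and 552 fell, with 11 of 21 neutrophil, 11 of 15 goblet, 9 of 17 T cell and 11 of 16 macrophage genes higher and 9 of 11 mitochondrial, 7 of 13 smooth muscle and 5 of 15 fatty acid oxidation genes lower. Without the libraries with squamous transcripts 599 rose and 676 fell, with 9 neutrophil, 7 T cell and 7 macrophage genes up.

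Saline D100 against Control covers the latest day. Goblet cell genes were again higher, 11 of 15 (12 adjusted over the list alone, fry adjusted p = 4.67e-05, adjusted p = 0.0241 with an estimated correlation), with Muc2 (chromosome 7, 141690340 to 141754693) going from 2462 ± 177 to 18780 ± 5533 CPM (log2 2.93 ± 0.197, edgeR adjusted p = 6.86e-07) and Agr2, a secretory chaperone, up by 1.69. Retnlb reached 1219 ± 347 CPM, Ang4 2683 ± 559 CPM, Pla2g4c 596 ± 358 CPM and Itln1 61.2 ± 20.5 CPM. The bombesin receptor gene Grpr rose from 0.135 ± 0.114 to 9.82 ± 2.02 CPM. Genes of the unfolded protein response, which adjusts protein folding in the endoplasmic reticulum, rose in 12 of 15 cases (13 adjusted over the list alone, fry adjusted p = 0.000267, adjusted p = 0.0984 with an estimated correlation), among them Creld2 (1.92) and Pdia6 (1.29). Heat shock genes rose in 9 of 10 cases (9 adjusted over the list alone, fry adjusted p = 0.00125, adjusted p = 0.126 with an estimated correlation), with Hsph1 going from 44.4 ± 10.6 to 293 ± 15.6 CPM and Hspa1a from 10.8 ± 5.29 to 82.4 ± 11.6 CPM.

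The interferon response list had 13 of 17 members up at D100 (16 adjusted over the list alone, fry adjusted p = 0.00139, adjusted p = 0.126 with an estimated correlation), with Mx1 at 50.7 ± 6.24 CPM and Stat2 up by 1.46. Smooth muscle genes fell in 12 of 13 cases (12 adjusted over the list alone, fry adjusted p = 0.00139, adjusted p = 0.155 with an estimated correlation), with Acta2 at log2 -0.87 and Smtn at -0.86. Leading the falls were genes higher in Control replicates 1 and 3 than in replicate 2, among them Cst6, at least 537-fold lower, and the desaturase Scd3 (27.3 ± 24.4 to 0.377 ± 0.131 CPM). Other falls were in the skeletal muscle genes Tnnt3 (76.5 ± 74.5 to 1.20 ± 1.11 CPM) and Mybpc1 (to 0.659 ± 1.02 CPM), Sec14l4 (6.53 ± 3.69 to 0.130 ± 0.168 CPM) and Sdr16c6 (9.72 ± 8.37 to 0.240 ± 0.248 CPM). At D100, 2057 genes rose and 1886 fell. With the smooth muscle score as a covariate 183 and 108 did, while median log2 fold changes went from 0.83 to 0.72 and from -0.73 to -0.61 and median SEs from 0.180 to 0.322 and from 0.162 to 0.286. Without the libraries with squamous transcripts 475 rose and 515 fell, with 6 unfolded protein response and 4 heat shock genes up and 4 smooth muscle genes down, while 1359 rose without Control replicate 1 and 1244 fell without saline D100 replicate 3.

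APX3330 against Control asks which changes were present in the treated animals of the model. Goblet cell genes rose in 13 of 15 cases (13 adjusted over the list alone, fry adjusted p = 8.77e-05, adjusted p = 0.0117 with an estimated correlation), with Ang4 at 2196 ± 1247 CPM, Retnlb at 646 ± 400 CPM, Itln1 at 41.9 ± 22.9 CPM, Pnliprp2 at 115 ± 87.0 CPM and Pla2g4c at 63.8 ± 33.3 CPM. Genes of the unfolded protein response rose in 12 of 15 cases (12 adjusted over the list alone, fry adjusted p = 0.00205, adjusted p = 0.110 with an estimated correlation), with Pdia6 up by 1.10 and Creld2 by 1.34. Smooth muscle genes fell in 12 of 13 cases (12 adjusted over the list alone, fry adjusted p = 0.000379, adjusted p = 0.103 with an estimated correlation), with Cnn1 going from 881 ± 19.7 to 451 ± 45.3 CPM and Acta2 from 2008 ± 40.1 to 1010 ± 171 CPM. Enteric neuron and glia genes fell in 8 of 14 cases (10 adjusted over the list alone, fry adjusted p = 0.000379, adjusted p = 0.103 with an estimated correlation), with Prph at log2 -0.97. Circadian clock genes fell in 7 of 15 cases (8 adjusted over the list alone, fry adjusted p = 0.00213, adjusted p = 0.110 with an estimated correlation), such as Per1 (-1.07) and Tef (-1.25). Krt1, Trp63, Them5, Myh8, Lgals7 and Krtdap, all carried by Control replicates 1 and 3, led the falls, while the squamous epithelium list was not called (7 of 12 members fell, 12 adjusted over the list alone, fry adjusted p = 0.0810, adjusted p = 0.409 with an estimated correlation). Krt1 was at least 2379-fold, Trp63 at least 100-fold and Them5 at least 70.7-fold lower. Myh8 had 13414 counts against 1 (ratio 13556, interval 2433 to 535466), Lgals7 1204 against 1 (ratio 1217, interval 218 to 48098) and Krtdap 746 against 1 (ratio 754, interval 135 to 29816). In all, 1291 genes rose and 1475 fell. The smooth muscle covariate left 21 and 2, while median log2 fold changes went from 0.66 to 0.59 and from -0.84 to -0.59 and median SEs from 0.148 to 0.341 and from 0.182 to 0.409. Without the libraries with squamous transcripts 146 rose and 236 fell, with 10 goblet genes and 1 unfolded protein response gene up and 9 smooth muscle genes, 1 enteric neuron and glia gene and 1 clock gene down. Leaving out Control replicate 1 or 3 or APX3330 replicate 2 or 3 gave 688 to 853 higher and 781 to 1012 lower genes.

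Genes called in the same direction in all 3 saline groups against Control numbered 949 higher and 738 lower, and in these and APX3330 557 higher and 475 lower. Independent lists of these sizes would share 29.8 and 22.9 genes over the saline groups and 2.13 and 1.87 over the 4 groups. The 3 Control libraries are too few to split, so part of the overlap can come from sharing them. Across the 5 groups 6737 genes differed by edgeR's F test.

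**Figure D3:**
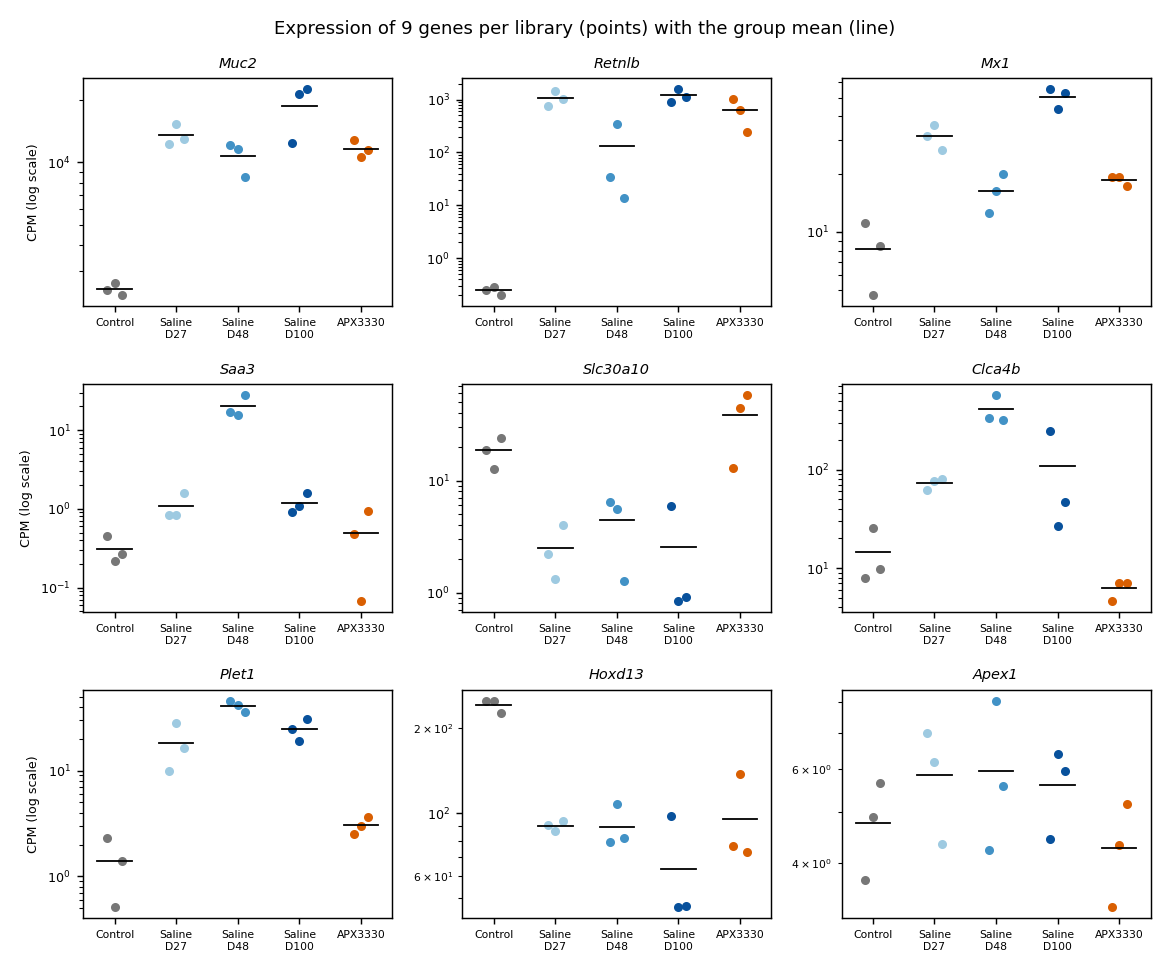
Expression of 9 genes in each library in CPM on a log axis (points), by group, with the group mean (line). Slc30a10 is at 12.8 to 58.4 CPM in APX3330 and at most 6.48 CPM in the saline libraries, and Clca4b is at 4.59 to 7.10 CPM in APX3330 and at least 26.6 CPM in the saline libraries.

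APX3330 against saline D27 asks what differed between the treated group and the first saline day. The transporter Slc30a10, which exports manganese (chromosome 1, 185454848 to 185468762), led the rises, from 2.52 ± 1.39 to 38.6 ± 23.4 CPM (log2 3.92 ± 0.729, edgeR adjusted p = 0.00835). The clock repressor Nr1d1 rose from 29.1 ± 10.2 to 95.1 ± 28.9 CPM. Zbtb16 rose from 6.94 ± 1.65 to 23.9 ± 12.2 CPM, Depp1 from 1.99 ± 0.652 to 7.47 ± 2.05 CPM and the cytochrome P450 gene Cyp2c69 from 1.12 ± 0.468 to 5.46 ± 0.399 CPM. Genes of fat cells led the falls. Plin1 fell from 8.36 ± 5.10 to 0.450 ± 0.664 CPM, Adipoq from 8.32 ± 5.11 to 0.495 ± 0.858 CPM. Cfd fell from 50.2 ± 32.6 to 2.83 ± 3.98 CPM and Car3 from 41.9 ± 25.2 to 2.45 ± 2.48 CPM, with Cyp2e1 falling from 12.2 ± 6.16 to 1.10 ± 1.45 CPM. Clca4b, a calcium-activated chloride channel regulator family gene (chromosome 3, 144910921 to 144932529), fell from 73.1 ± 10.1 to 6.25 ± 1.44 CPM.

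Of 11 adipocyte genes 9 fell and Pparg rose (10 and 1 adjusted over the list alone, fry adjusted p = 0.0211, adjusted p = 0.322 with an estimated correlation). Smooth muscle genes fell in 12 of 13 cases (13 adjusted over the list alone, fry adjusted p = 0.00468, adjusted p = 0.218 with an estimated correlation), such as Lmod1 (-0.80) and Smtn (-0.81). Enteric neuron and glia genes fell in 6 of 14 cases (11 adjusted over the list alone, fry adjusted p = 0.000308, adjusted p = 0.0866 with an estimated correlation), with Prph at log2 -1.20 and Vip at -1.02. In the interferon response list 5 of 17 genes fell (10 adjusted over the list alone, fry adjusted p = 0.0348, adjusted p = 0.324 with an estimated correlation), with the antiviral gene Rsad2 going from 33.8 ± 4.83 to 12.0 ± 2.63 CPM and Isg15 from 74.8 ± 26.6 to 22.1 ± 5.53 CPM. In total 850 genes rose and 788 fell. Leaving out saline D27 replicate 1 or 2 or APX3330 replicate 2 or 3 gave between 139 and 263 higher and between 223 and 268 lower genes, and without the libraries with squamous transcripts 434 were higher and 483 lower, with 6 enteric neuron and glia genes lower. With the smooth muscle score as a covariate edgeR called 2 higher genes and 1 lower, while median log2 fold changes went from 0.46 to 0.50 and from -0.77 to -0.73 and median SEs from 0.112 to 0.212 and from 0.179 to 0.329. With the adipocyte score it called 0, at median folds of 0.32 and -0.58 and median SEs of 0.194 and 0.310.

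APX3330 against saline D48 gave 1697 genes higher and 1860 lower. With the adipocyte score as a covariate there were 148 and 264, while median log2 fold changes went from 0.50 to 0.42 and from -0.93 to -0.74 and median SEs from 0.119 to 0.169 and from 0.209 to 0.299. Inflammatory genes were lower with APX3330, 16 of 17 on the neutrophil and acute inflammation list (17 adjusted over the list alone, fry adjusted p = 0.000102, adjusted p = 0.0382 with an estimated correlation). Saa3 fell to 0.493 ± 0.436 CPM (log2 -5.34 ± 0.519, edgeR adjusted p = 3.36e-05), Lcn2, an iron-binding neutrophil protein, from 15.8 ± 4.22 to 2.04 ± 0.853 CPM and Nos2 to 8.59 ± 0.761 CPM. Fibroblast and matrix genes fell in 12 of 17 cases (15 adjusted over the list alone, fry adjusted p = 0.000102, adjusted p = 0.0453 with an estimated correlation), with the collagens Col1a1 and Col1a2 at log2 -1.11 and -1.07. NF-kB targets fell in 12 of 16 cases (13 adjusted over the list alone, fry adjusted p = 0.000974, adjusted p = 0.0893 with an estimated correlation), such as Vcam1 (-1.21) and Icam1 (-1.25). Macrophage and dendritic cell genes fell in 10 of 16 cases (11 adjusted over the list alone, fry adjusted p = 0.00164, adjusted p = 0.0980 with an estimated correlation), with C1qa at log2 -1.25.

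Mast cell genes fell in 4 of 7 cases and Kit rose (5 and 1 adjusted over the list alone, fry adjusted p = 0.00122, adjusted p = 0.0980 with an estimated correlation). Kit is also carried by the pacemaker cells of the gut wall, while Mcpt1, a mucosal mast cell protease, fell from 12.1 ± 7.67 to 0.224 ± 0.141 CPM. Fatty acid oxidation genes rose in 9 of 15 cases (10 adjusted over the list alone, fry adjusted p = 0.000811, adjusted p = 0.0893 with an estimated correlation), with Cpt1a up by 0.70. Leading the rises were Dmp1 (0.592 ± 0.197 to 5.50 ± 3.89 CPM), Slc30a10 (from 4.43 ± 2.77 CPM), Ankrd40cl (1.74 ± 1.34 to 12.8 ± 5.31 CPM). Next came Cyp2c69 (from 0.821 ± 0.509 CPM) and Mptx1 (1568 ± 1342 to 10210 ± 4364 CPM). The falls were led by the pancreatic enzymes Cela2a (to 0.247 ± 0.320 CPM) and Try5 (to 0.338 ± 0.585 CPM) and Prss22, at least 87.5-fold lower. The neutrophil gene S100a9 had 591 counts against 2 (ratio 279, interval 76.9 to 2311), the Wnt inhibitor Notum 226 against 1 (ratio 214, interval 37.9 to 8470) and Mcpt2 235 against 2 (ratio 111, interval 30.4 to 922). Notum was uneven between the saline D48 libraries, at 4.92 ± 5.97 CPM. Without saline D48 replicates 2 and 3, which held the pancreatic transcripts, 321 genes were higher and 530 lower, with 11 neutrophil, 8 fibroblast, 9 NF-kB, 7 macrophage, 3 mast cell and 1 fatty acid oxidation gene called. Leaving out saline D48 replicate 3 or APX3330 replicate 2 gave 1040 to 1059 higher and 1089 to 1146 lower genes.

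APX3330 against saline D100 gave 55 higher and 36 lower genes, with 2387 genes at an unadjusted p below 0.05. Plet1, a marker of regenerating epithelium (chromosome 9, 50494525 to 50505482), fell from 24.8 ± 5.82 to 3.04 ± 0.560 CPM (log2 -3.02 ± 0.382, edgeR adjusted p = 0.00288). Mcpt1 fell from 8.11 ± 3.34 CPM, Plin1 from 5.98 ± 1.58 CPM, Cidec, a lipid droplet protein, from 9.14 ± 2.14 to 1.01 ± 0.315 CPM, Sptssb from 19.8 ± 12.5 to 2.04 ± 0.629 CPM and Clca4b from 108 ± 123 CPM. Slc30a10 rose from 2.56 ± 2.93 CPM, Serpina9 from 1.48 ± 0.266 to 4.40 ± 1.24 CPM and Mettl7a3 from 2.18 ± 0.594 to 5.92 ± 1.07 CPM. Other rises were the protease Pcsk4 from 4.64 ± 0.407 to 12.1 ± 1.64 CPM, Naaladl1 from 13.9 ± 3.32 to 34.7 ± 5.43 CPM and Tsku from 10.7 ± 2.40 to 24.6 ± 3.48 CPM. In the lists, 2 of 17 interferon response genes fell, Rsad2 and Mx1 (13 adjusted over the list alone, fry adjusted p = 0.0478, adjusted p = 0.148 with an estimated correlation), and 2 of 7 mast cell genes, Mcpt1 and Mcpt2 (3 adjusted over the list alone, fry adjusted p = 0.0188, adjusted p = 0.110 with an estimated correlation). Of 11 adipocyte genes 3 fell (10 adjusted over the list alone, fry adjusted p = 0.0256, adjusted p = 0.118 with an estimated correlation). Leaving out saline D100 replicate 2 or 3 or APX3330 replicate 2 or 3 left 4 to 7 higher and 5 to 11 lower genes, and without the libraries with squamous transcripts 15 were higher and 22 lower. DESeq2 called 198 and 228. With the adipocyte score as a covariate edgeR called 0, while median log2 fold changes of the 55 and 36 genes went from 0.80 to 0.74 and from -1.47 to -1.08 and median SEs from 0.142 to 0.246 and from 0.236 to 0.378.

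Against each of the 3 saline groups, 20 genes were higher with APX3330 and 21 lower, and 0 and 0 with either the smooth muscle or the adipocyte score as a covariate. For all genes called against saline D27, median folds went from 0.46 to 0.50 and from -0.77 to -0.73 under the smooth muscle score. Their median SEs went from 0.112 to 0.212 and from 0.179 to 0.329. The adipocyte score gave median folds of 0.32 and -0.58 and median SEs of 0.194 and 0.310. The higher ones included Slc30a10, the serotonin transporter gene Slc6a4 (24.7 ± 7.35 CPM against 11.3 to 15.7 in the saline means), the peroxisomal oxidase Hao2 (377 ± 64.7 against 135.5 to 196.3 CPM). Others were the acetyl-CoA-producing enzymes Acly (657 ± 112 against 438 to 494 CPM) and Acss2 (150 ± 9.03 against 88.9 to 114 CPM). The lower ones included Plet1, Clca4b, Plin1, Cidec, Mcpt1, Mcpt2, the complement gene C3 (207 ± 62.4 against 401 to 714 CPM) and the interferon-induced genes Ifit2 (14.3 ± 5.20 against 33.7 to 53.9 CPM) and Oasl1 (31.8 ± 4.85 against 55.8 to 75.0 CPM). Slc6a4, Hao2, Acly, Acss2, C3, Ifit2 and Oasl1 were picked from these 41 genes after their values were seen. Independent lists would share 0.244 higher and 0.162 lower genes. Part of the overlap can come from the APX3330 libraries that all 3 comparisons use. Without saline D100 replicate 2 the counts were 0 and 6, and without APX3330 replicate 3 they were 0 and 4. Without the libraries with squamous transcripts they were 5 and 12, and without saline D48 replicates 2 and 3 they were 11 and 22.

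Fold changes across genes in APX3330 against a saline group ran opposite to those of that saline group against Control, as sharing the saline libraries alone produces. The correlation over 18038 genes, which are not independent replicates, was -0.309 for D27, -0.528 for D48 and -0.297 for D100, against -0.496, -0.496 and -0.503 in simulated unchanged groups. The covariance was -0.180, -0.478 and -0.187, against -0.0816, -0.0816 and -0.0838 in the simulations, a difference of -0.0985, -0.396 and -0.103. Pancreatic transcripts of saline D48 replicates 2 and 3 add to the D48 value. Cela2a, for instance, was fitted at log2 17.95 in saline D48 against Control and -13.0 in APX3330 against saline D48. As Cela2a had no count in Control, the first value is set by the fit and is not a measured fold. The relation was not computed without these libraries, so the size of the D48 value cannot be read as an effect of APX3330. In the simulations no gene differed between groups. A saline group that differs from both others, also by day or tissue, would add to the size of the covariance. The D27 and D100 values therefore cannot be read as an effect of APX3330 either.

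Between the saline days, D48 stood apart in inflammation and matrix. Against D27, 4 of 17 neutrophil and acute inflammation genes rose at D48 (16 adjusted over the list alone, fry adjusted p = 0.00176, adjusted p = 0.0166 with an estimated correlation), with Saa3 going from 1.09 ± 0.451 to 20.3 ± 6.89 CPM (log2 4.21 ± 0.472, edgeR adjusted p = 0.00153) and Lcn2 from 4.55 ± 0.746 to 15.8 ± 4.22 CPM. Of 17 fibroblast and matrix genes 5 rose (12 adjusted over the list alone, fry adjusted p = 0.00176, adjusted p = 0.0358 with an estimated correlation), Mmp2 by 1.00 and Col1a1 by 0.74. Of 14 enteric neuron and glia genes 1 fell, Prph by 0.86 on the log2 scale (8 adjusted over the list alone, fry adjusted p = 0.00176, adjusted p = 0.0391 with an estimated correlation). Pancreatic enzymes led the rises, with Cela3b at 45853 counts against 1 (ratio 47052, interval 8445 to 1858500), Cpa1 (from 0.102 ± 0.0289 to 1539 ± 1945 CPM) and Cela2a (from 0.147 ± 0.0965 to 2089 ± 2604 CPM). Kirrel3os fell from 4.34 ± 2.07 to 0.571 ± 0.612 CPM, the enterocyte gene Tmigd1 from 10.7 ± 2.37 to 1.75 ± 0.397 CPM and Mptx1 from 7792 ± 948 to 1568 ± 1342 CPM. In all 154 genes rose and 90 fell. The smooth muscle covariate left 0 of either, while median log2 fold changes went from 0.81 to 0.78 and from -0.89 to -0.74 and median SEs from 0.158 to 0.255 and from 0.172 to 0.257. Without saline D27 replicate 2 there were 19 and 5, and without D48 replicates 2 and 3 there were 12 and 12, with 2 neutrophil and 3 fibroblast genes up and 0 enteric neuron and glia genes down.

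At D100 heat shock genes were higher than at D27: 6 of 10 rose (8 adjusted over the list alone, fry adjusted p = 0.0292, adjusted p = 0.204 with an estimated correlation), with Hspa1b going from 74.7 ± 25.1 to 399 ± 21.6 CPM (log2 2.42 ± 0.420, edgeR adjusted p = 0.0115) and Hspa1a from 15.3 ± 5.54 to 82.4 ± 11.6 CPM. Hspa1a and Hspa1b are near-identical copies, so their separate values are uncertain. Cyp2c69 rose from 1.12 ± 0.468 to 4.76 ± 0.484 CPM. The scavenger receptor gene Marco had 193 counts at D27 and 2 at D100 (ratio 85.5, interval 23.4 to 711). Its D27 libraries were uneven, at 4.26 ± 5.29 CPM. Mir145a fell from 4.87 ± 1.27 to 1.47 ± 0.210 CPM and Gchfr from 4.75 ± 0.304 to 1.57 ± 0.300 CPM. In all 294 genes rose and 262 fell. The smooth muscle covariate left 2 and 1, while median log2 fold changes went from 0.50 to 0.52 and from -0.65 to -0.59 and median SEs from 0.109 to 0.162 and from 0.140 to 0.201. Leaving out D27 replicate 1 gave 17 and 20, D100 replicate 3 gave 14 and 17, and D27 replicate 3 gave 514 higher genes. Without the libraries with squamous transcripts 34 rose and 29 fell, with 2 heat shock genes up.

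At D100 against D48 the inflammatory and matrix genes were lower again. On the neutrophil list 13 of 17 genes fell (14 adjusted over the list alone, fry adjusted p = 0.000222, adjusted p = 0.0366 with an estimated correlation), with Saa3 at log2 -4.08 and Lcn2 at -2.62. Of 17 fibroblast and matrix genes 12 fell (13 adjusted over the list alone, fry adjusted p = 0.000222, adjusted p = 0.0366 with an estimated correlation), with Col1a1 going from 631 ± 49.0 to 287 ± 10.3 CPM (edgeR adjusted p = 7.58e-05). Mitochondrially encoded genes rose in 9 of 10 cases (9 adjusted over the list alone, fry adjusted p = 0.00365, adjusted p = 0.170 with an estimated correlation), such as mt-Nd4 from 933 ± 77.7 to 1648 ± 11.8 CPM. Tmigd1 rose from 1.75 ± 0.397 to 20.4 ± 4.52 CPM, Pla2g4c from 51.8 ± 86.6 to 596 ± 358 CPM and the lipid transporter Abca12 from 0.260 ± 0.280 to 3.83 ± 2.76 CPM. The pancreatic enzymes Ctrb1, Pnlip and Cela2a were at least 52469-fold, 36619-fold and 29347-fold lower at D100. In all 1298 genes rose and 1155 fell. Without D48 replicates 2 and 3 there were 230 and 269, with 4 neutrophil, 6 fibroblast and 3 mitochondrial genes called. Without the libraries with squamous transcripts there were 710 and 652, and leaving out saline D48 replicate 3 or saline D100 replicate 2 or 3 gave 705 to 825 higher and 625 to 864 lower genes.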

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

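The covariate of adipocyte genes and both fits without sets of libraries were chosen after seeing the data, and the other alternatives before the data were examined. DESeq2 size factors in place of TMM left the counts of genes within 1.5 times and ended 0 of 269 calls of named genes, and the DESeq2 test ended 1 of 267. The smooth muscle covariate ended 137 of these calls without a change of sign, the adipocyte covariate 77 and limma-voom 56. Genes whose fold change changed sign under a tissue score are not in these numbers and are given below. Leaving out the libraries with squamous transcripts ended 64 of 257, and leaving out those with pancreatic transcripts 37 of 269. The cause was not tested for limma-voom. Where a fit leaves 1 library in a group, that library is assumed to vary like those of the other groups. Samples share only a number: of 30 cross-group pairs with the same number 2 had r above 0.1, and 3 of 15 libraries correlated best with their own number. With the replicate block 10 calls of named genes ended, and 124 of 143 list calls held with 1 new. The counts of genes given for each alternative are those that moved by more than 1.5 times.

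Given the smooth muscle score as a covariate, there were 1124 higher and 1005 lower in saline D27 against Control, 39 higher and 18 lower in saline D48 against Control, 183 higher and 108 lower in saline D100 against Control, 21 higher and 2 lower in APX3330 against Control. Further counts were 2 higher and 1 lower in APX3330 against saline D27, 31 higher in APX3330 against saline D100, 0 higher and 0 lower in saline D48 against saline D27, 2 higher and 1 lower in saline D100 against saline D27. It also gave 4487 genes differing among the 5 groups, 0 higher and 0 lower in APX3330 against all 3 saline groups. Requiring a change of at least 1 on the log2 scale, there were 863 higher and 409 lower in saline D27 against Control, 1265 higher and 656 lower in saline D48 against Control, 873 higher and 617 lower in saline D100 against Control, 392 higher and 575 lower in APX3330 against Control. Counts also moved to 63 higher and 265 lower in APX3330 against saline D27, 215 higher and 831 lower in APX3330 against saline D48, 20 higher and 22 lower in APX3330 against saline D100, 62 higher and 35 lower in saline D48 against saline D27. The same setting gave 31 higher and 54 lower in saline D100 against saline D27, 199 higher and 311 lower in saline D100 against saline D48, 3 higher and 12 lower in APX3330 against all 3 saline groups. Given the adipocyte score as a covariate, there were 1025 higher and 849 lower in saline D27 against Control, 524 higher and 650 lower in APX3330 against Control, 0 higher and 0 lower in APX3330 against saline D27, 148 higher and 264 lower in APX3330 against saline D48. Other counts became 0 higher and 0 lower in APX3330 against saline D100, 54 lower in saline D48 against saline D27, 0 higher and 0 lower in APX3330 against all 3 saline groups. Without Control replicates 1 and 3 and saline D100 replicate 1, there were 210 higher and 200 lower in saline D27 against Control, 599 higher and 676 lower in saline D48 against Control, 475 higher and 515 lower in saline D100 against Control, 146 higher and 236 lower in APX3330 against Control. Also changed were 434 higher and 483 lower in APX3330 against saline D27, 15 higher and 22 lower in APX3330 against saline D100, 44 lower in saline D48 against saline D27, 34 higher and 29 lower in saline D100 against saline D27. Further counts were 710 higher and 652 lower in saline D100 against saline D48, 3088 genes differing among the 5 groups, 5 higher and 12 lower in APX3330 against all 3 saline groups. Without saline D48 replicates 2 and 3, there were 984 higher and 552 lower in saline D48 against Control, 321 higher and 530 lower in APX3330 against saline D48, 12 higher and 12 lower in saline D48 against saline D27, 230 higher and 269 lower in saline D100 against saline D48. It also gave 11 higher in APX3330 against all 3 saline groups. With only the 2 groups of a comparison in the fit, there were 333 higher in APX3330 against saline D27, 916 higher and 1105 lower in APX3330 against saline D48, 57 lower in APX3330 against saline D100, 38 higher and 11 lower in saline D48 against saline D27. Counts also moved to 161 higher in saline D100 against saline D27, 13 higher in APX3330 against all 3 saline groups. By limma-voom with sample quality weights, there were 1745 higher and 1377 lower in APX3330 against saline D27, 262 higher and 155 lower in saline D48 against saline D27, 1137 higher and 757 lower in saline D100 against saline D27, 10 lower in APX3330 against all 3 saline groups. Without a filter on low counts, there were 1323 lower in APX3330 against saline D27, 256 higher and 520 lower in APX3330 against saline D100, 561 higher and 350 lower in saline D48 against saline D27, 531 higher and 655 lower in saline D100 against saline D27. The same setting gave 88 higher and 218 lower in APX3330 against all 3 saline groups. By the DESeq2 test, there were 1185 lower in APX3330 against saline D27, 198 higher and 228 lower in APX3330 against saline D100, 401 higher and 302 lower in saline D48 against saline D27, 726 higher and 562 lower in saline D100 against saline D27. Other counts became 64 higher and 80 lower in APX3330 against all 3 saline groups. Under the replicate block, there were 24 higher in APX3330 against saline D100, 9 higher in APX3330 against all 3 saline groups. The cause was not tested, except that fits without libraries have fewer samples and that SEs grew under the tissue scores where most calls ended. For APX3330 against saline D27 the median SE of the genes called lower went from 0.179 to 0.329 under the smooth muscle score. Their median log2 fold change went from -0.77 to -0.73. Under the adipocyte score the median SE was 0.310 and the median fold -0.58, so there the folds shrank as well.

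Leaving out each library in turn gave 1022 to 1756 higher and 777 to 1566 lower for saline D27 against Control, 1909 to 2209 higher and 1641 to 2249 lower for saline D48 against Control, 1359 to 1763 higher and 1244 to 1745 lower for saline D100 against Control, 688 to 1267 higher and 781 to 1321 lower for APX3330 against Control. The ranges were 139 to 1037 higher and 223 to 853 lower for APX3330 against saline D27, 1040 to 1583 higher and 1089 to 1626 lower for APX3330 against saline D48, 4 to 48 higher and 5 to 30 lower for APX3330 against saline D100, 19 to 156 higher and 5 to 91 lower for saline D48 against saline D27. The ranges were 14 to 514 higher and 17 to 274 lower for saline D100 against saline D27, 705 to 935 higher and 625 to 1076 lower for saline D100 against saline D48, 5330 to 6986 genes differing among the 5 groups, 0 to 19 higher and 4 to 21 lower for APX3330 against all 3 saline groups.

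Under the smooth muscle score as a covariate, 0 of the 10 comparisons were called for absorptive colonocyte (from 1), Wnt target and crypt base (from 3), Notch pathway (from 1), proliferation (from 1), B cell (from 1), smooth muscle (from 5), enteric neuron and glia (from 6), heat shock (from 5). Under the smooth muscle score as a covariate, 1 of the 10 comparisons was called for enteroendocrine and tuft cell (from 4), Paneth cell (from 3), MHC class II (from 4), cytotoxic lymphocyte (from 4), endothelium (from 4), adipocyte (from 3), circadian clock (from 4), unfolded protein response (from 4). Under the smooth muscle score as a covariate, 2 of the 10 comparisons were called for NF-kB target (from 5), AP-1 subunit and immediate early gene (from 5), IL-22 and STAT3 target (from 5), NRF2 target (from 4), interferon response (from 5), T cell (from 4), macrophage and dendritic cell (from 5), exocrine pancreas (from 4). Under the smooth muscle score as a covariate, 3 of the 10 comparisons were called for regenerative epithelium and YAP target (from 5), plasma cell (from 7), xenobiotic metabolism (from 5). Under the smooth muscle score as a covariate, 4 of the 10 comparisons were called for fibroblast and extracellular matrix (from 7). Under camera with an estimated correlation, 0 of the 10 comparisons were called for absorptive colonocyte (from 1), enteroendocrine and tuft cell (from 4), Wnt target and crypt base (from 3), Notch pathway (from 1), regenerative epithelium and YAP target (from 5), Paneth cell (from 3), proliferation (from 1), NF-kB target (from 5), AP-1 subunit and immediate early gene (from 5), IL-22 and STAT3 target (from 5), NRF2 target (from 4), interferon response (from 5), MHC class II (from 4), T cell (from 4), cytotoxic lymphocyte (from 4), B cell (from 1), plasma cell (from 7), macrophage and dendritic cell (from 5), mast cell (from 7), smooth muscle (from 5), endothelium (from 4), adipocyte (from 3), exocrine pancreas (from 4), fatty acid oxidation and PPAR target (from 6), xenobiotic metabolism (from 5), circadian clock (from 4), heat shock (from 5), unfolded protein response (from 4), mitochondrially encoded gene (from 6). Under camera with an estimated correlation, 1 of the 10 comparisons was called for enteric neuron and glia (from 6). Under camera with an estimated correlation, 3 of the 10 comparisons were called for neutrophil and acute inflammation (from 6), fibroblast and extracellular matrix (from 7). Under the replicate block, 0 of the 10 comparisons were called for Notch pathway (from 1), B cell (from 1). Under the replicate block, 1 of the 10 comparisons was called for adipocyte (from 3). Under the replicate block, 3 of the 10 comparisons were called for IL-22 and STAT3 target (from 5), interferon response (from 5).

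Fold changes that changed sign were those of squamous, muscle, neuron, clock and fat genes under a tissue score: Krt1 0.95 (saline D48 against Control), Krtdap 0.55 (saline D48 against Control), Myh8 1.34 (APX3330 against Control), Them5 1.26 (APX3330 against Control), Krtdap 0.23 (APX3330 against Control), Snap25 0.20 (APX3330 against Control), Tef 0.10 (APX3330 against Control) with the smooth muscle score as a covariate, and Cfd 0.33 (APX3330 against saline D27), Car3 0.55 (APX3330 against saline D27), Adipoq 0.71 (APX3330 against saline D27) with the adipocyte score as a covariate.

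For Apex1, which was uncalled throughout, some alternatives changed the sign of the fold change. The log2 fold change of Apex1, Saline_D27 vs Control, was 0.30 and became -0.00397 with the smooth muscle score as a covariate. Likewise, the log2 fold change of Apex1, Saline_D48 vs Control, was 0.32 and became -0.70 with the smooth muscle score as a covariate and -0.16 without saline D48 replicates 2 and 3. The log2 fold change of Apex1, Saline_D100 vs Control, was 0.24 and became -0.68 with the smooth muscle score as a covariate. Likewise, the log2 fold change of Apex1, APX3330 vs Saline_D48, was -0.48 and became 0.0112 without saline D48 replicates 2 and 3. The log2 fold change of Apex1, Saline_D48 vs Saline_D27, was 0.0237 and became -0.0288 under the replicate block, -0.14 by limma-voom, -0.69 with the smooth muscle score as a covariate and -0.47 without saline D48 replicates 2 and 3, and ran from -0.25 to 0.21 with each library left out in turn. Likewise, the log2 fold change of Apex1, Saline_D100 vs Saline_D27, was -0.0638 and became 0.0790 without Control replicates 1 and 3 and saline D100 replicate 1, and ran from -0.24 to 0.0901 with each library left out in turn. The log2 fold change of Apex1, Saline_D100 vs Saline_D48, was -0.0875 and became 0.0196 with the smooth muscle score as a covariate, 0.0584 without Control replicates 1 and 3 and saline D100 replicate 1 and 0.40 without saline D48 replicates 2 and 3, and ran from -0.28 to 0.18 with each library left out in turn.

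Small changes were often missed: in simulated counts for saline D27 against Control over 17656 genes, 30% of 50 genes changed 1.5-fold, 40% at 2-fold, 80% at 4-fold and 96% at 8-fold were recovered. For APX3330 against saline D100 over 17636 genes these were 34%, 56%, 80% and 88%, with 6.52% of the calls false, against 3.15%.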

Other observations

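The tests of tissue dilution, of the stretch of colon and of the pancreatic list, the adipocyte covariate, the folds and SEs under both covariates, and the tests on other splits of the libraries, were chosen after the results were seen, and the 4 tests of adipose tissue and smooth muscle before, although a condition on their spread over genes was added after.

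Of the 41 genes that differed between APX3330 and each of the 3 saline groups, 29 were not called between APX3330 and Control. For 26 the saline groups were all called in the opposite direction against Control, and 21 of these were not called between APX3330 and Control. The 41 genes were chosen on the same saline libraries, which alone favours opposite directions. No number to be found without a change was computed for the 26 or the 21, so they do not show a return to Control levels. A p that misses the threshold does not show that these levels were equal. Posterior homeobox genes chosen after their values were seen were highest in Control. Hoxd9 had a mean of 11.7 CPM in Control and 1.56 to 3.87 CPM in the other groups, and Hoxd12 15.2 and 2.37 to 6.29 CPM. Hoxb13 had a mean of 399 CPM in Control and 299, 333, 201 and 283 CPM in saline D27, D48, D100 and APX3330, and Hoxa13 65.7 CPM in Control and 34.4, 34.9, 52.4 and 49.4 CPM.

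Goblet cell genes were higher in the 3 saline groups and APX3330 than in Control. Other tissue diluting the epithelium would lower goblet and absorptive genes alike, but the goblet minus absorptive score shifted by 2.99 to 3.39 on the log2 scale, against a within-group SD of 0.496. The goblet score is a mean over 15 genes and weighs Retnlb and Ang4 heavily. At D27 these were up by log2 12.04 and 11.33, against a median goblet shift of 1.37 over the saline and APX3330 groups. A different stretch of colon would tie goblet genes to the posterior Hox genes within groups. That slope gave 12.8% of the median goblet shift of 1.37 (-10.0 to 21.4 with a library left out, SD over genes 30.8). The Hox score of the other groups differed from Control by -1.44, against a within-group SD of 0.3665. The slope therefore reaches far beyond the spread it was fitted on and cannot decide. The stretch of colon stays open, and AOM and DSS, day of collection and the open treatment of Control remain as untested explanations.

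Pancreatic enzyme transcripts were high in saline D48 replicates 2 and 3, as with Cel at 4254 and 897 CPM and at most 1.82 CPM elsewhere. Of a second list of 16 pancreatic genes, 1 of which is also in the first list, 87.5% lay above the other 13 libraries in both, while Sycn and Klk1 reached 534 and 1097 CPM elsewhere. Their log2 ratios between the replicates had a median of 1.91 and an SD of 0.358, so they moved in nearly one proportion. Pancreatic tissue or RNA in these libraries is a candidate explanation, and when it entered was not tested.

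Genes lower and higher in APX3330 than in saline D27 were set against less adipose tissue and less smooth muscle, since the adipocyte score was lower by 2.70 in size and the smooth muscle score by 0.768. For the higher genes the within-group slope on the adipocyte score gave 13.3% of the median fold (-3.65 to 20.1 with a library left out, SD over genes 68.2). That on the smooth muscle score gave -18.4% (-39.0 to -5.85, SD 105). Each was short of 100% by more than the SD, which is a spread over genes and not an error of the slope. Quartiles ran from -19.3 to 43.0 and from -64.1 to 29.7. The score shifts lie far beyond the within-group SDs of 0.589 and 0.123, so the slopes cannot decide for the higher genes. For the lower genes the slopes on the 2 scores gave 0.519% (-4.83 to 9.98, SD 104) and -3.21% (-9.78 to 5.22, SD 123), medians near 0 of slopes that go both ways. Their SD lay above their distance to 100% although the upper quartiles were 34.6 and 60.8. By the rule set before, without the later condition on this SD, both results would have counted against these tissues. The score shifts reach as far beyond the within-group SDs here, so neither tissue can be told apart from treatment for the lower genes. The smooth muscle covariate left 2 higher genes and 1 lower, as median SEs went from 0.112 to 0.212 and from 0.179 to 0.329 with median folds going from 0.46 to 0.50 and from -0.77 to -0.73. The adipocyte covariate left 0, with median SEs of 0.194 and 0.310 and folds of 0.32 and -0.58, and day of collection and treatment stay open as untested.

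For each 3 against 3 comparison, 10 splits are too few for a share under 0.05, and 1 split, the real one, gave as many calls. The real counts, with the highest of the other splits, were 3522 and 0 for saline D27 against Control, 4916 and 1 for saline D48 against Control, 3943 and 90 for saline D100 against Control, and 2766 and 0 for APX3330 against Control. They were 1638 and 0 for APX3330 against saline D27, 3557 and 10 against saline D48, and 91 and 0 against saline D100. Between days they were 244 and 0 for D48 against D27, 556 and 0 for D100 against D27, and 2453 and 0 for D100 against D48. Over 100 splits of the 15 libraries, 1 gave as many genes differing among 5 groups as the real 6737 (highest other 806). For the overlaps only the saline and APX3330 libraries were regrouped, with Control kept. There 1 of 100 reached 20 genes higher in APX3330 than in each saline group (highest other 0). For genes lower, 1 of 100 reached 21 (highest other 1). Random labelling of all 15 libraries would thus seldom give 6737 genes, if the libraries came from separate animals. On the same condition, random labelling of the saline and APX3330 libraries alone would seldom give the 20 and 21. Most splits mix groups that differ from each other, which can itself lower their counts. The splits therefore cannot decide whether the overlaps of 20 and 21 genes are beyond chance for APX3330 itself.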
